A study of Mus musculus with 6 samples.

How the data were processed

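Droplet-based RNA profiles from the lateral habenula region were measured in 6 libraries, 3 from mice after chronic restraint stress (CRS) and 3 from naive mice, and each library was taken as 1 sample of its group as the labels give it. The deposited matrices hold raw UMI counts per gene and barcode, not normalised, with 55357 features named by Ensembl gene ID and symbol. Per the file headers the matrices came from Cell Ranger 7.1.0; the submitters' processing notes name Cell Ranger 7.2.0, bcl2fastq 5.0.1, Seurat 4.1.1 and the genome build GRCm39. Genes were identified by the IDs and symbols of the files, and no coordinates are given. No barcode held under 500 UMIs.

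Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrially encoded UMIs. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest scores were removed at a share of 0.8% per 1000 barcodes, which took 1145, 1266 and 830 cells from CRS 1, CRS 2 and CRS 3 and 808, 914 and 1287 from naive 1, naive 2 and naive 3. Kept cells numbered 10821, 11316 and 9354 in the CRS and 9244, 9774 and 11397 in the naive libraries, and their median numbers of genes were 1481, 1386 and 1974 and 1895, 2155 and 1705. Counts were scaled to 10000 UMIs per cell and log-transformed, 3000 highly variable genes (without mitochondrially encoded, sex-linked and haemoglobin genes) were reduced to 40 principal components, and a shared-neighbour graph over 20 neighbours was clustered with leidenalg 0.10.2 at resolution 1. No correction between libraries was applied before clustering. Python was 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

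Clusters were named from marker lists. A non-neuronal cluster needed a mean marker excess of 1 log2 unit over the median cluster and at least 3 markers at 2-fold; neurons needed at least 3 general markers over the non-neuronal cells and a subtype excess of 0.5 log2 units, and habenular subtypes also Pou4f1 at 3-fold over the thalamic clusters. A non-neuronal cluster was left unnamed where its median UMI count was over 3 times below the mean of its libraries' medians and none of its 10 leading genes was a marker of the class, which applied to cluster 27. A class was tested where each library gave at least 20 cells, which left 8 classes. The thalamic class included a cluster (12) with a marker of another class and none of its own among its 10 leading genes, so its clusters 12 and 17 were tested one by one. Clusters left unnamed took part in the totals of cells. They were in no test, except that neurons without a subtype were part of the alternative with all neuron-like cells. Names such as "astrocyte-like" rest on these markers alone.

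UMI counts were summed per library and class and tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, robust quasi-likelihood F test, two-sided, Benjamini-Hochberg within a class, threshold 0.05), with DESeq2 1.42.0 beside it. With 3 libraries against 3, 4 residual degrees of freedom were left, or 3 with a term for the library set. Fold changes are CRS over naive. Classes were also compared in their share of the kept cells with the edgeR test on cell counts and an exact two-sided permutation test, whose smallest p is 0.1. A list of 25 gene groups was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, where at least 3 members were measured, and again with the correlation estimated from the data, for which statmod 1.5.0 was present. The list for endothelial cells was not tested because the class was too small. The groups of genes, the markers, the tests and the rule for naming genes were fixed before the data were examined.

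Under that rule, a class with fewer than 3 genes past the threshold has the genes with the smallest p in each direction named and said not to pass, 6 in lateral habenula neuron-like cells and 3 in any other class. Mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked genes were left out of that ranking. Besides, 14 genes were named in lateral habenula neuron-like cells and Kcnj10 in astrocyte-like cells whatever their result, and up to 3 members with the smallest p for each gene group past its threshold. Other genes named in the text, among them Gabarapl2, Atg4d and the marker genes of clusters, were chosen after their values were seen.

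The tests were checked on simulated data, in which each gene was drawn independently and without library sets. The simulated lists therefore do not show how often a list is called in the real counts, where its genes can move together. With 200 changed genes among counts like those of lateral habenula neuron-like cells, 4 of 67 genes changed 1.5-fold, 29 of 67 changed 2-fold and 61 of 66 changed 4-fold were called, with 17 false calls. Of the genes changed 2-fold, 22 of 67 were called in medial habenula neuron-like, 15 in astrocyte-like, 11 in oligodendrocyte-like and 8 in microglia-like cells. With no change 0 genes were called in lateral habenula neuron-like, 1 in medial habenula neuron-like, 1 in oligodendrocyte-like, 4 in astrocyte-like and 2 in microglia-like cells, and 1 gene list was called in microglia-like cells. A shift of 0.3 log2 units in 75 genes was called with a preset (adjusted p = 7.22e-15) and an estimated correlation (0.0368) in lateral habenula neuron-like cells, while in microglia-like cells, with 10 of the genes measured, it was missed (0.381 and 0.545). Beside the shifted list, 2 other lists were called in microglia-like and 1 in astrocyte-like cells. A 2-fold change in a share was called where the dispersion was set to 0.02 (adjusted p = 0.00483). It was missed at 0.482 (adjusted p = 0.138), the common dispersion estimated from the real cell counts of the named classes.

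The alternatives tried were DESeq2's Wald test and size factors, no filter on low counts, the replicate number as a block, each library left out in turn, a stricter cell filter (at least 1000 UMIs and at most 10% mitochondrially encoded UMIs), removal of 2 times as many doublets, resolution 2 (47 clusters), counts thinned to equal totals, all neuron-like cells as 1 class, TMM normalisation of cell counts, and fry in place of camera. A term for the library set, fits within each set, and fibroblast-like cluster 21 alone were added after seeing the data. Summed totals per library ran from 2145000 to 2967000 UMIs in astrocyte-like, 152800 to 2096000 in choroid plexus, 65250 to 629200 in fibroblast-like, 17030000 to 21100000 in medial habenula neuron-like, 115600 to 227000 in microglia-like and 2438000 to 3173000 in oligodendrocyte-like cells, 533400 to 617200 in oligodendrocyte precursors, 1296000 to 5555000 in cluster 12 and 171900 to 4228000 in cluster 17.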

Results

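The lateral habenula is a small nucleus of the epithalamus whose neurons respond to aversive events. Per the labels, droplet-based RNA profiles were made from this region in naive mice and in mice after chronic restraint stress (CRS), a repeated confinement used as a rodent model of depression-like states. The study title puts the question in terms of neuronal autophagy. There were 6 libraries, 3 from CRS mice and 3 from naive mice, with 68158 barcodes, of which 61906 were kept as cells. Total UMIs per library were 42714511, 39573033 and 56747095 for CRS 1, CRS 2 and CRS 3, and 47234507, 65155485 and 56540037 for naive 1, naive 2 and naive 3. The median kept cell held 2798, 2554 and 4153 UMIs in the CRS libraries and 4002, 4723.5 and 3327 UMIs in the naive libraries. The labels call the assay single-nucleus sequencing, while the protocol text in them describes enzymatic dissociation into whole cells. The median share of mitochondrially encoded UMIs per kept cell lay between 0 and 0.0660% in the 6 libraries. Here "cell" stands for a kept barcode. Nothing in the labels says that the libraries came from separate animals, so the p-values measure the spread between these samples.

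The habenula and its surroundings were recovered as 36 clusters, 29 of which carried the markers of a cell class. Medial habenula neuron-like cells, named by a marker list that includes Tac2, Nwd2 and Chrna3, made up the largest class with 23509 cells, followed by 9994 oligodendrocyte-like, 7946 astrocyte-like and 6725 lateral habenula neuron-like cells. The lateral habenula class joined clusters 9, 11, 13 and 22, and cluster 22 was led by the activity-dependent genes Fosb, Fos, Npas4 and Arc. Cluster 9, with 2597 cells, had the medial habenula marker Nwd2 at 4123 CPM, against 291, 641 and 323 in clusters 11, 13 and 22. Its Htr2c, a lateral habenula marker, was higher (3688 CPM against 368, 1243 and 199), while its Gap43 and Chrm3, from the same list, were lower. The mean marker excess of clusters 9, 11, 13 and 22 was 0.69, 0.68, 0.73 and 0.60 log2 units against the 0.5 required. The name of this class is therefore less certain. Smaller classes held 3351 thalamic neuron-like cells, 1413 oligodendrocyte precursors, 1211 ependymal, 1161 choroid plexus epithelial, 779 fibroblast-like, 762 microglia-like, 247 mural, 89 border macrophage-like, 70 hippocampal or cortical neuron-like and 36 endothelial cells. A further 4404 neurons were given no subtype.

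Oligodendrocyte-like cells made up 17.6% ± 0.947 (SD, n = 3) of cells in CRS and 14.5% ± 1.08 in naive libraries, a log2 ratio of 0.27 ± 0.12 (SE), and every CRS library lay above every naive library. Border macrophage-like cells are the resident macrophages of the meninges and perivascular spaces. They made up 0.174% ± 0.0435 in CRS and 0.115% ± 0.00337 in naive libraries and did not overlap either, with 14 cells in CRS 2 and 11 in naive 1. Their shares did overlap with the stricter cell filter, where CRS 2 (0.0592%) lay below naive 1 (0.0787%). They also did with 2 times as many doublets removed, where CRS 1 (0.0620%) lay below naive 2 (0.0903%). Oligodendrocyte-like shares overlapped in neither setting. With all kept cells, neither class passed the edgeR test over 14 classes (adjusted p = 0.491 for both). The exact permutation p was 0.1 for both, the smallest that 3 against 3 can give. The oligodendrocyte log2 ratio was 0.33 within CRS 1, CRS 2 and naive 1 and 0.18 within CRS 3, naive 2 and naive 3. Lateral habenula neuron-like cells made up 10.6% ± 0.712 in CRS and 11.2% ± 1.18 in naive libraries (adjusted p = 0.722). Medial habenula neuron-like cells made up 39.5% ± 5.68 and 36.2% ± 4.16. Naive 1 held 542 of the 1161 choroid plexus cells and 1 of the 1211 ependymal cells. Of the clusters left unnamed, cluster 10, with Tfap2d, Glra3 and Gad2 among its leading genes, made up 2.40% ± 0.539 in CRS and 4.58% ± 2.07 in naive libraries. Cluster 18 made up 1.58% ± 0.382 and 1.48% ± 0.287, and cluster 19 1.48% ± 0.154 and 1.37% ± 0.202, in the same order. Cluster 26 made up 0.325% ± 0.117 and 0.421% ± 0.174, cluster 27 0.274% ± 0.346 and 0.390% ± 0.421, and cluster 28 0.416% ± 0.425 and 0.164% ± 0.0921.

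**Figure D1:**
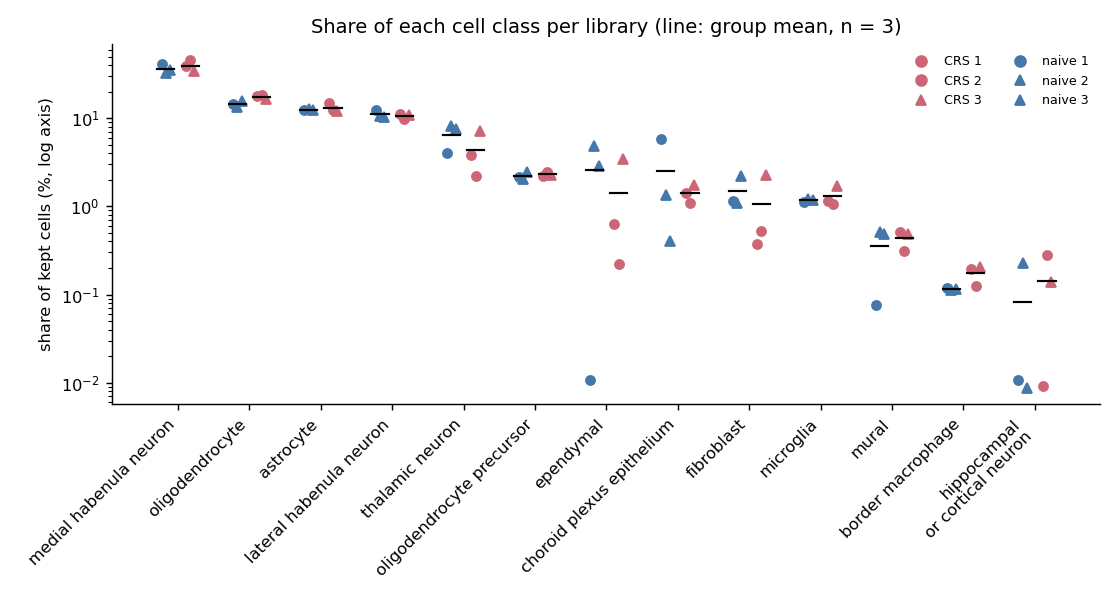
Share of each cell class among the kept cells of a library, in percent on a log axis, with naive libraries in blue, CRS libraries in red and group means (n = 3) as lines; circles are CRS 1, CRS 2 and naive 1, and triangles are CRS 3, naive 2 and naive 3, and the endothelial class of 36 cells is not drawn. Oligodendrocyte-like cells averaged 17.6% in CRS and 14.5% in naive libraries, and no class passed the test.

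The libraries fell into sets that cross the groups. In lateral habenula neuron-like sums, the first principal component held 48.2% of the variance and parted CRS 1, CRS 2 and naive 1 (the first set) from CRS 3, naive 2 and naive 3 (the second set) (r2 = 0.975 for the sets and 0.103 for the groups). The second set had 520 genes higher and 1563 lower by edgeR in this class. It differed in 3434 genes in medial habenula neuron-like, 2817 in astrocyte-like and 2383 in oligodendrocyte-like cells. In the first set, transcripts named as opposite strand took 0.501% ± 0.0270 of UMIs (SD, n = 3) against 0.287% ± 0.0273 in the second, and Gm and Rik genes 7.19% ± 0.146 against 5.40% ± 0.217. The nuclear transcript Malat1 took 7.43% ± 2.02 against 4.42% ± 0.857, and mitochondrially encoded genes 0.0670% ± 0.0455 against 0.180% ± 0.0556. For the latter, CRS 1 had 0.0170%, CRS 2 0.106%, CRS 3 0.207%, naive 1 0.0781%, naive 2 0.116% and naive 3 0.216%. Each call on mitochondrially encoded genes given below ended when CRS 1 was left out. Values within each set therefore stand beside the pooled ones. Within a set the lone library of a group was assumed to vary like the other group.

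**Figure D2:**
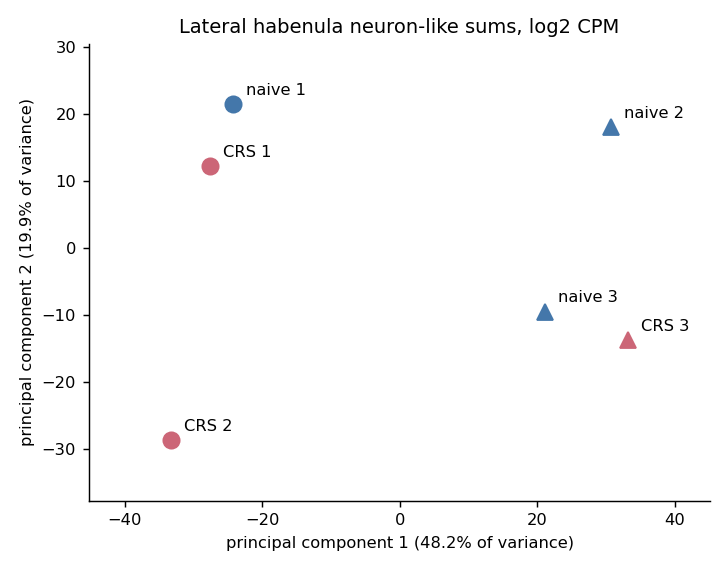
First and second principal components of log2 CPM in the lateral habenula neuron-like sums, 1 point per library, with CRS in red and naive in blue, circles for the first set and triangles for the second. CRS 1, CRS 2 and naive 1 lie on the left and CRS 3, naive 2 and naive 3 on the right of an axis that holds 48.2% of the variance.

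In lateral habenula neuron-like cells, genes for the respiratory chain and for ribosomes rose in CRS and genes for transmitter receptors, synaptic scaffolds and burst firing channels fell, each by a small amount (3 CRS against 3 naive libraries, camera with a preset correlation). None of these lists was called with an estimated correlation (adjusted p = 0.876 for each), and those that fell were not called with the library set as a term either. Of 75 nuclear genes of oxidative phosphorylation, which makes most cellular ATP, 65 were higher, with a median log2 fold change of 0.18 (adjusted p = 5.03e-04; 0.876 with an estimated correlation). Ndufa10, a complex I subunit, went from 48.7 ± 5.06 to 65.6 ± 10.2 CPM (SD, n = 3; log2 fold change 0.43 ± 0.14, SE), with no overlap between groups. The ATP synthase subunits Atp5a1 and Atp5j2 had 0.45 ± 0.17 and 0.32 ± 0.15. Of 81 ribosomal protein genes 62 were higher (median 0.09, adjusted p = 0.0116; 0.876 with an estimated correlation), among them Rpl6 at 0.46 ± 0.19, Rps27l at 0.63 ± 0.29 and Rpl30 at 0.37 ± 0.18. Adjusted over the list alone, 0 members of the lists called in this class passed.

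All 14 measured GABA receptor genes were lower in CRS (median −0.14, adjusted p = 0.0116; 0.876 with an estimated correlation), led by Gabrb2 at −0.29 ± 0.12, Gabrg1 at −0.39 ± 0.17 and Gabra2 at −0.22 ± 0.12. Of 27 glutamate receptor genes 7 were higher and the rest lower (median −0.11, adjusted p = 0.0116; 0.876 estimated), with the metabotropic receptor Grm4 at −0.51 ± 0.22 and the kainate receptor subunit Grik1 at −0.30 ± 0.14. Synaptic scaffold genes, 9 of 36 higher, had a median of −0.11 (adjusted p = 0.0116; 0.876 estimated), with Dlg3 at −0.35 ± 0.21, Nlgn1 at −0.18 ± 0.12 and Shank3 at −0.21 ± 0.15. Of 18 burst firing channels 3 were higher (median −0.10, adjusted p = 0.0352; 0.876 estimated). Cacna1i, a T-type calcium channel that drives bursts, went from 129.0 ± 7.05 to 102.1 ± 11.4 CPM (−0.34 ± 0.12) without overlap. It was also among the 10 leading genes of cluster 11, which is part of this class. Cluster 11 made up 3.14% ± 0.262 (SD) of kept cells in CRS and 3.72% ± 0.890 in naive libraries. Whether the makeup of the class by cluster accounts for the lower Cacna1i was not tested. Kcnq3 and Kcnn2 had −0.20 ± 0.13 and −0.17 ± 0.11. Of 10 mitochondrially encoded genes 2 were higher (median −0.17, adjusted p = 0.0352; 0.876 estimated), with mt-Nd6 at −0.62 ± 0.60, mt-Atp6 at 0.54 ± 0.75 and mt-Atp8 at −0.56 ± 0.88.

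Measured beside these groups, Malat1 took 5.82% ± 1.79 of UMIs in CRS and 3.98% ± 0.698 in naive lateral habenula neuron-like sums, and choroid plexus markers had 87.3 ± 10.0 and 114.1 ± 102.2 CPM. Oligodendrocyte markers had 132.3 ± 53.6 and 145.6 ± 66.3 CPM, and astrocyte markers 110.6 ± 26.1 and 122.0 ± 22.9 CPM. Within the first and the second set, the medians were 0.28 and 0.11 for oxidative phosphorylation, 0.22 and 0.09 for ribosomal proteins, and −0.23 and −0.01 for GABA receptors. They were −0.06 and 0.02 for glutamate receptors, −0.01 and 0.06 for scaffolds, −0.04 and −0.05 for burst firing channels, and −0.18 and 0.46 for mitochondrially encoded genes. With the set as a term, oxidative phosphorylation (adjusted p = 1.72e-04) and ribosomal proteins (0.00358) were still called, though not with an estimated correlation besides (0.869). GABA receptors (0.0797), glutamate receptors (0.361), scaffolds (0.650), burst firing channels (0.502) and mitochondrially encoded genes (0.554, test lower but median 0.14) were not. Leaving out CRS 2 ended every call but that of the mitochondrially encoded genes, with adjusted p of 0.281 for GABA receptors, 0.314 for oxidative phosphorylation, glutamate receptors and burst firing channels, and 0.363 for scaffolds, and with the direction turned for ribosomal proteins. Leaving out naive 2 ended every call but that of GABA receptors, with 0.101 for mitochondrially encoded genes, 0.128 for oxidative phosphorylation and glutamate receptors, 0.187 for scaffolds, 0.201 for burst firing channels and 0.989 for ribosomal proteins. The call on ribosomal proteins also ended without CRS 3 (0.188) and naive 1 (0.369), and that on scaffolds without CRS 1 (0.0785) and naive 3 (0.0792). That on burst firing channels ended without CRS 1 (0.0875) and naive 3 (0.212), with no low-count filter (0.108) and at equal depth (0.0553). That on mitochondrially encoded genes ended without naive 3 (0.215) and, with the direction turned, without CRS 1.

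**Figure D3:**
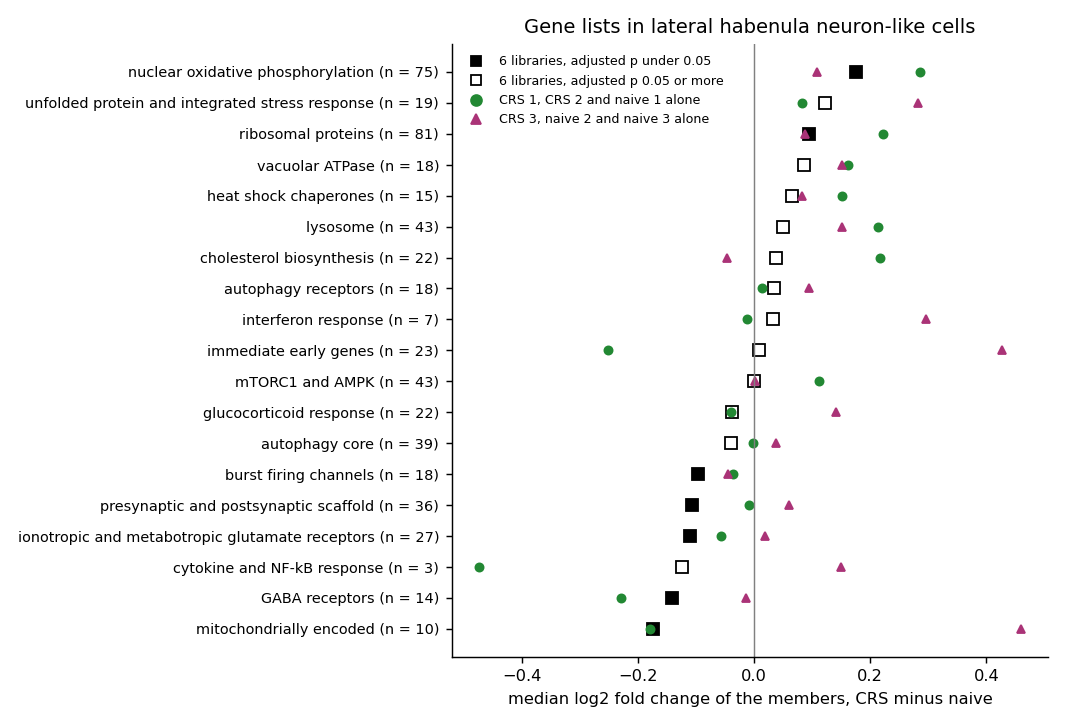
Median log2 fold change, CRS minus naive, of the members of each gene list in lateral habenula neuron-like cells (n is the number of genes measured), as squares over all 6 libraries (filled when the adjusted p was under 0.05) and as circles and triangles within the first and the second set. Oxidative phosphorylation lies to the right of 0 in all 3 fits at 0.18, 0.28 and 0.11, while glutamate receptors lie at −0.11, −0.06 and 0.02.

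Autophagy genes, the subject of the study title, did not pass as a group in lateral habenula neuron-like cells. Of 39 core autophagy genes 16 were higher, and the test pointed lower with a median of −0.04 while their mean was 0.01 (adjusted p = 0.806). Gabarapl2, which lipidates onto autophagosome membranes, went from 31.7 to 45.2 CPM (0.51 ± 0.15), and Atg4d, the protease that processes this family, from 19.5 to 26.5 CPM (0.44 ± 0.17). Neither passed (adjusted p = 0.969). Autophagy receptors had 10 of 18 members higher (median 0.03, adjusted p = 0.637), and lysosomal genes 28 of 43 (0.05, 0.162). Vacuolar ATPase genes, which acidify the lysosome, had 14 of 18 members higher (0.09, 0.237), and mTORC1 and AMPK genes 22 of 43 (median 0.0004 and mean 0.02 with the test lower, adjusted p = 0.877). With the set as a term, the lysosomal list (median 0.15, adjusted p = 0.00356; 0.21 and 0.15 within the sets) and the vacuolar ATPase list (0.16, 0.0218; 0.16 and 0.15) were called higher. Neither was with an estimated correlation besides (0.869 for the lists of this class).

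Among the genes fixed for this class, Sqstm1 (ENSMUSG00000015837), the selective autophagy receptor p62, went from 46.5 ± 8.96 to 66.2 ± 8.95 CPM (log2 fold change 0.51 ± 0.16, n = 3 against 3), with 0.68 within the first and 0.49 within the second set, and did not pass (adjusted p = 0.969). Map1lc3b, which encodes the autophagosome marker LC3B, had 0.07 ± 0.20, Becn1 −0.12 ± 0.13, Atg7 −0.04 ± 0.15 and Ulk1 −0.15 ± 0.20. Mtor had −0.18 ± 0.15, the AMPK subunit Prkaa2 −0.19 ± 0.15 and the lysosomal transcription factor Tfeb 0.02 ± 0.32. The AMPA receptor subunit Gria1 had −0.14 ± 0.12, Gria2 0.01 ± 0.10 (−0.001 with DESeq2 size factors) and the NMDA receptor subunit Grin2a −0.07 ± 0.13. The glucocorticoid-induced Fkbp5 had −0.17 ± 0.16, the T-type channel Cacna1g −0.18 ± 0.14 and Camk2b −0.21 ± 0.14. None of the 14 passed.

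**Figure D4:**
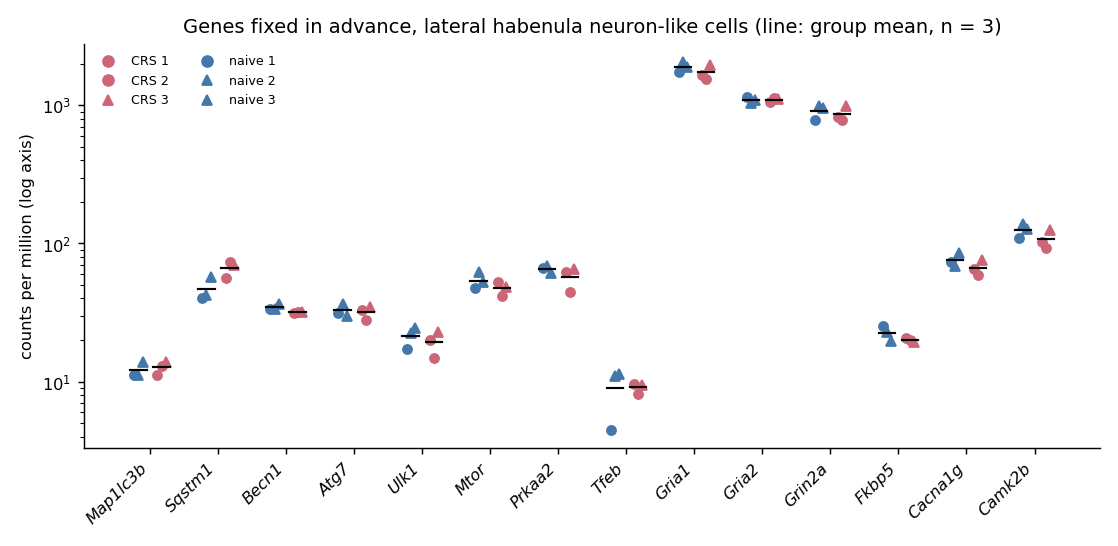
CPM (log axis) of the 14 genes fixed for lateral habenula neuron-like cells, 1 point per library with the marks of the other plots and the group mean (n = 3) as a line. Sqstm1 averaged 46.5 in naive and 66.2 in CRS libraries, and no gene passed the test.

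No single gene passed in lateral habenula neuron-like cells. The genes with the smallest p among those higher in CRS were Gm50213 (ENSMUSG00000117882, 1.23 ± 0.27), Rps12-ps9 (2.53 ± 0.56, from 0.268 to 1.59 CPM), Gcnt7 (1.07 ± 0.26), the mitochondrial ribosomal protein gene Mrpl21 (0.71 ± 0.18), the prohibitin gene Phb (0.98 ± 0.27) and 4921515G04Rik (0.91 ± 0.25). Those lower were Slc35f5 (−0.62 ± 0.17), 9530026P05Rik (−0.45 ± 0.12) and Slc17a8 (ENSMUSG00000019935, −1.03 ± 0.29), the vesicular glutamate transporter VGLUT3, from 6.38 to 3.11 CPM. Like Cacna1i, 9530026P05Rik was among the 10 leading genes of cluster 11. Also lower were Gm42869 (−0.94 ± 0.27), Nox4 (−1.03 ± 0.30) and Chrna7 (ENSMUSG00000030525, −0.41 ± 0.13), the α7 nicotinic receptor subunit, from 39.8 ± 0.540 to 29.9 ± 1.56 CPM. All 12 separated the 3 CRS from the 3 naive libraries, as did 1495 of the 16511 genes tested (9.06%, against 10% by chance), and the smallest adjusted p was 0.969. At an unadjusted p under 0.05 edgeR had 572 genes, 359 higher and 213 lower, where chance gives 825.6. DESeq2 had 343 and 0 after adjustment. The summed totals per library ran from 4950000 to 8364000 UMIs.

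The remaining lists tested in this class held stress and immune genes. Glucocorticoid response genes had 9 of 22 members higher (median −0.04, adjusted p = 0.246), immediate early genes 12 of 23 (median 0.009 with the test lower, 0.404; −0.25 and 0.43 within the sets), and heat shock chaperones 11 of 15 (0.06, 0.637). Genes of the unfolded protein and integrated stress response had 15 of 19 members higher (0.12, 0.151; 0.0162 with the set as a term, and 0.869 with an estimated correlation besides). Interferon response genes had 4 of 7 members higher (0.03, 0.447), cytokine and NF-kB genes 1 of 3 (−0.12, 0.694), and cholesterol biosynthesis genes 13 of 22 (0.04, 0.264).

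Medial habenula neuron-like cells, which are mostly cholinergic or peptidergic, had 4 of the lists named above called, while ribosomal proteins, burst firing channels and mitochondrially encoded genes were not. Oxidative phosphorylation genes rose, 65 of 75 higher with a median of 0.15 (adjusted p = 9.45e-04; 0.951 with an estimated correlation), among them Cox7b at 0.36 ± 0.15, Atp5a1 at 0.36 ± 0.17 and Atp5l at 0.23 ± 0.11. GABA receptor genes fell, 0 of 15 higher (median −0.17), as did glutamate receptors, 2 of 28 higher (−0.13), and scaffolds, 6 of 36 higher (−0.09; adjusted p = 0.00457 for each of the 3, and 0.951 with an estimated correlation). Examples were Gabrd at −0.84 ± 0.51, Gabra4 at −0.70 ± 0.45, Gabra2 at −0.17 ± 0.12 and Grm4 at −0.59 ± 0.32. Others were Grik3 at −0.31 ± 0.19, Grik2 at −0.25 ± 0.16, Shank2 at −0.27 ± 0.12, Homer1 at −0.24 ± 0.13 and Pclo at −0.21 ± 0.11. Within the first and second sets the medians were 0.27 and 0.07 for oxidative phosphorylation, −0.13 and 0.06 for GABA receptors, −0.10 and 0.05 for glutamate receptors and −0.04 and 0.04 for scaffolds. With the set as a term only oxidative phosphorylation stayed called (3.02e-04, against 0.461, 0.461 and 0.637). Without CRS 2 all 4 calls ended (0.264), and so they did without naive 2 (0.321 for oxidative phosphorylation, 0.0856, 0.145 and 0.185 for the others in this order). The first also ended without CRS 3 (0.0509) and naive 1 (0.149), the other 3 without CRS 1 (0.0982, 0.0946 and 0.114), and that on GABA receptors without naive 3 (0.0648). None of 19300 genes passed by edgeR or DESeq2 (521 and 358 at an unadjusted p under 0.05). The smallest p belonged to Gm32916 (2.36 ± 0.52), Gm42477 (0.71 ± 0.18) and Zfp799 (0.52 ± 0.13) among higher genes and Gm43088 (−1.10 ± 0.28), Zfp217 (−0.92 ± 0.25) and Camk1d (−0.57 ± 0.17) among lower ones. Among the 15 other lists the mitochondrially encoded genes came nearest, 1 of 12 higher (−0.37, 0.0543).

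Astrocyte-like cells had nuclear oxidative phosphorylation genes higher, 56 of 75 (median 0.11, adjusted p = 0.00912), and mitochondrially encoded genes lower, 0 of 9 higher (−0.55, 1.66e-04); with an estimated correlation the adjusted p was 0.949 for both. Ndufa8 had 0.53 ± 0.28, Sdhb 0.41 ± 0.23 and Cox7b 0.31 ± 0.18, and mt-Nd6 −1.66 ± 0.54, mt-Atp8 −0.79 ± 0.51 and mt-Nd5 −0.75 ± 0.61. Within the first and the second set the medians were 0.33 and 0.03 for the former list and −1.16 and 0.16 for the latter. Both stayed called with the set as a term (5.07e-04 and 0.00829). The former call ended without CRS 2 (0.600), CRS 3 (0.647), naive 1 (0.670) and naive 2 (0.505), the latter without CRS 1 (0.188). Kcnj10, the potassium channel Kir4.1, had 162.9 ± 21.4 CPM in naive and 166.5 ± 16.7 in CRS libraries (0.03 ± 0.14). Astrocyte homeostasis genes had 8 of 18 members higher (median −0.02 with a mean of 0.004, adjusted p = 0.867) and reactivity genes 6 of 10 (0.13, 0.867). Astrocyte markers themselves had 4880 ± 287.6 CPM in CRS and 5384 ± 130.2 in naive sums and neuroblast markers 20.7 ± 3.05 and 28.3 ± 2.97, without overlap. Of 201 such sums over all classes 9 did not overlap, where chance gives 10%. Of 13631 genes none passed (354 by edgeR and 142 by DESeq2 at an unadjusted p under 0.05). The proteasome subunit Psma3 (0.55 ± 0.14), Cfl2 (0.57 ± 0.15) and Aldh2 (0.58 ± 0.15) came first among higher genes and Lama3 (−1.81 ± 0.45), Gm21860 (−1.16 ± 0.29) and Gm10635 (−0.65 ± 0.18) among lower ones.

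In oligodendrocyte-like cells mitochondrially encoded genes were lower, 1 of 10 higher (median −0.35, adjusted p = 0.00342; 0.986 with an estimated correlation), with mt-Nd6 at −0.93 ± 0.46, mt-Atp6 at −0.81 ± 0.63 and mt-Co1 at −0.44 ± 0.71. The medians within the sets were −0.92 and 0.49, and the call ended with the set as a term (0.0754) and without CRS 1 (0.783). Myelin genes had 13 of 20 members higher (0.04, 0.716) and glucocorticoid response genes 19 of 24 (0.23, 0.0988). No gene passed among 12731 (331 and 178 at an unadjusted p under 0.05). The list was led by Nmrk1 (1.19 ± 0.22, from 10.1 ± 0.310 to 23.3 ± 3.28 CPM), which makes NAD from nicotinamide riboside, 1700042O10Rik (1.15 ± 0.22) and Taz (0.59 ± 0.14) among higher genes and Synpr (−0.58 ± 0.14), Gm12239 (−1.32 ± 0.35) and Ddx10 (−0.51 ± 0.14) among lower ones. Endothelial markers in these sums had 3.47 CPM in CRS and 8.66 in naive libraries and did not overlap. Oligodendrocyte precursors had 0 of 13 lists and 0 of 7250 genes past the threshold (287 by edgeR and 105 by DESeq2 at an unadjusted p under 0.05). Dusp15 (0.83 ± 0.20), Utp6 (1.25 ± 0.32) and 4930419G24Rik (1.15 ± 0.32) came first among higher and Cyp7b1 (−0.57 ± 0.17), Adgrv1 (−0.69 ± 0.21) and Dab2 (−0.75 ± 0.23) among lower genes.

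Microglia-like cells likewise had mitochondrially encoded genes lower, 0 of 5 higher (median −0.45, adjusted p = 0.0107; 0.971 with an estimated correlation), with mt-Co1 at −1.10 ± 0.81, mt-Nd1 at −0.60 ± 1.10 and mt-Nd4 at −0.44 ± 1.05. In counts simulated for this class with no change, 1 list was called as well. The medians within the sets were −2.09 and 0.52, with the set as a term the adjusted p was 0.0424, and the call ended without CRS 1 (0.431) and naive 2 (0.0845). Homeostatic microglia genes had 4 of 14 members higher (−0.12, 0.485) and disease-associated genes 0 of 8 (−0.30, 0.432), so neither list passed. None of 3288 genes passed (60 and 35 at an unadjusted p under 0.05). The death receptor gene Tnfrsf21 (1.11 ± 0.29), Dhx30 (1.00 ± 0.29) and Gm34280 (0.96 ± 0.29) came first among higher and the immune checkpoint gene Vsir (−0.61 ± 0.18), Slx4ip (−0.98 ± 0.30) and Lars2 (−1.03 ± 0.32) among lower genes.

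The largest shift of any list was in fibroblast-like cells with their clusters 21 and 29 joined. In these collagen-producing cells of the meninges and stroma, immediate early genes rose in CRS. Of 14 measured, 13 were higher, with a median log2 fold change of 0.80 (adjusted p = 6.14e-07; 0.690 with an estimated correlation). The adjusted p was at most 9.01e-05 whichever library was left out, the only call of 24 in all classes that held so. With 2 times as many doublets removed, however, 0, 7 and 206 cells were left in CRS 1, CRS 2 and CRS 3. Naive 1, naive 2 and naive 3 then kept 57, 59 and 228, and the list could not be tested in that setting. Fos went from 36.4 ± 10.96 to 108.6 ± 79.0 CPM (1.29 ± 0.51) without overlap. Btg2 and Ier2 had 1.18 ± 0.49 and 1.12 ± 0.49. The median was 1.94 within the first and 0.09 within the second set, and the adjusted p with the set as a term 1.10e-05. The class joined clusters 21 and 29, which differ in Fos (64.2 and 2.05 CPM). Cluster 29 gave 0, 1 and 52 cells in CRS 1, CRS 2 and CRS 3 and 45, 41 and 35 in naive 1, naive 2 and naive 3. Cluster 21 gave 41, 59 and 161 and 60, 67 and 217. In cluster 21 alone, an analysis added after this was seen, 9 of 11 immediate early genes were higher (median 0.53, adjusted p = 0.00106, and 0.380 with an estimated correlation). That median was smaller in size than the −0.61 of mitochondrially encoded genes in choroid plexus cells, so the ranking holds for the joined class only.

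Vacuolar ATPase genes also rose in fibroblast-like cells, 10 of 13 higher (median 0.14, adjusted p = 0.0478; 0.690 with an estimated correlation; 0.0458 with the set as a term), with Atp6v1e1 at 0.88 ± 0.45, Atp6v0d1 at 0.61 ± 0.38 and Atp6v1h, against the list, at −0.79 ± 0.42. Mitochondrially encoded genes fell, 0 of 4 higher (−0.57, 0.0273; 0.690 with an estimated correlation; 0.0458 with the set as a term). Examples were mt-Nd4 at −0.62 ± 0.39, mt-Nd1 at −0.55 ± 0.42 and mt-Nd2 at −0.60 ± 0.46. With no low-count filter the adjusted p was 0.0637 and 0.238, and in cluster 21 alone the former had 0.0904. The medians of the former list were 0.72 and −0.07 within the sets, and that of the latter −0.52 within the second, the first measuring too few of its genes. The former call ended without CRS 1 (0.175), CRS 2 (0.238), CRS 3 (0.0940), naive 1 (0.277) and naive 2 (0.135). The latter ended without CRS 1 (0.175), CRS 2 (0.0701), naive 2 (0.117) and naive 3 (0.0668). No gene passed among 4513 (121 and 109 at an unadjusted p under 0.05). Arl5b (1.65 ± 0.41), Dstn (1.27 ± 0.36) and Pltp (1.48 ± 0.42) came first among higher and Mitf (−1.08 ± 0.25), Rapgef5 (−1.39 ± 0.37) and Npas3 (−1.69 ± 0.46) among lower genes. Mitf, a transcription factor of lysosomal genes, was the 1 gene past the threshold adjusted over the list alone, in the mTORC1 and AMPK list, which had 14 of 21 members higher (median 0.11, mean 0.002, adjusted p = 0.976) and in cluster 21 alone 4 of 14 (−0.31, 0.00183; 0.380 estimated).

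Choroid plexus epithelial cells, which secrete cerebrospinal fluid, had oxidative phosphorylation genes higher, 54 of 59 (median 0.30, adjusted p = 1.42e-04; 0.39 and 0.14 within the sets), and ribosomal protein genes higher, 29 of 35 (0.35, 0.0119; 0.63 and 0.24); with an estimated correlation the adjusted p was 0.889 for both. Mitochondrially encoded genes were lower, 0 of 6 higher (−0.61, 0.00655; 0.889 estimated; −0.78 and −0.30 within the sets). Examples were Atp5d at 1.16 ± 0.42, Cox7b at 0.69 ± 0.27, and Uqcr11 at 1.47 ± 0.59, then Rpl41 at 0.73 ± 0.26, Rps12 at 0.96 ± 0.39, and Rpl7l1 at 1.02 ± 0.45. Among mitochondrially encoded genes mt-Co1 was at −0.60 ± 0.48, mt-Nd5 at −0.62 ± 0.51 and mt-Nd2 at −0.66 ± 0.67. All 3 stayed called with the set as a term (7.41e-04, 0.0245 and 0.0396) and none at equal depth (0.0753, 0.776 and 0.0867). The first call ended without naive 2 (0.140), the second without CRS 2 (0.0621), naive 1 (0.299) and naive 2 (0.910), and the third without CRS 1 (0.176) and naive 3 (0.181). With 2 times as many doublets removed, naive 1, naive 2 and naive 3 kept 536, 118 and 0 choroid plexus cells. CRS 1, CRS 2 and CRS 3 then kept 149, 115 and 149, and the lists could not be tested in that setting. Of 7887 genes none passed (228 and 95 at an unadjusted p under 0.05). The clock gene Per3 (0.97 ± 0.22, from 77.7 ± 11.2 to 146.4 ± 22.2 CPM), Snw1 (0.98 ± 0.23) and Stx12 (1.14 ± 0.30) came first among higher and Ddhd1 (−0.64 ± 0.17), Hs6st2 (−0.64 ± 0.18) and Dnajc6 (−1.05 ± 0.30) among lower genes.

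Of the clusters in the thalamic neuron-like class, 12 and 17 had enough cells to be tested. Cluster 12 had 6 thalamic markers at 2-fold but 0 of them among its 10 leading genes, and 1 marker of another class there, so its name is less certain. In cluster 12, ribosomal protein genes rose, 58 of 76 higher (median 0.24, adjusted p = 5.70e-05; 0.746 with an estimated correlation; 0.25 and 0.05 within the sets), with Rpl10a at 0.86 ± 0.34, Rps27 at 0.69 ± 0.29 and Rpl5 at 0.60 ± 0.25. So did oxidative phosphorylation genes, 52 of 75 higher (0.14, 0.00426; 0.746 estimated; 0.25 and 0.09), with Cox7b at 0.70 ± 0.21, Atp5l at 0.51 ± 0.20 and Atp5a1 at 0.48 ± 0.19. Both stayed called with the set as a term (0.00832 and 0.00847) and ended without CRS 2 (0.435 and 0.543) and naive 2 (0.277 and 0.238). In cluster 17 ribosomal protein genes were called higher, 41 of 70 (0.10, 0.0425; 0.33 and 0.004 within the sets; 0.0117 with the set as a term; adjusted p = 0.940 with an estimated correlation). The members with the smallest p were Rpl17 at 0.60 ± 0.32, Rpl41 at −0.65 ± 0.37 and Rps25 at −0.74 ± 0.51. That call ended without CRS 3 (0.229), naive 1 (0.653) and naive 2 (0.420) and with no low-count filter (0.179), and its direction turned without CRS 2, which gave 21 cells. No gene passed among 12959 in cluster 12 (282 and 98 at an unadjusted p under 0.05) or among 11553 in cluster 17 (112 and 64). In cluster 12 D130079A08Rik (0.84 ± 0.21), Gm49599 (1.04 ± 0.28) and Gnl3 (0.66 ± 0.18) led the higher and Tle1 (−0.52 ± 0.13), Adamtsl3 (−0.93 ± 0.26) and Epha7 (−0.50 ± 0.15) the lower genes. In cluster 17 Gm12128 (1.55 ± 0.49), Mfap1b (1.14 ± 0.37) and Taf11 (1.15 ± 0.38) led the higher and Gm15155 (−1.24 ± 0.31), Gm4107 (−0.89 ± 0.26) and Man2a1 (−0.56 ± 0.17) the lower. Over all classes 24 of 158 list tests were called, 11 higher and 13 lower, 0 of them with an estimated correlation. With the set as a term 27 were called, 15 of them in both, and 0 with an estimated correlation besides. The median, the mean and the test of a list differed in sign in 40 of the 158, none of them called.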

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

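The tests on the library sets and on the oxidative phosphorylation genes were chosen after these results were seen; the comparison with other splits of the libraries was planned.

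The effect of CRS on a gene list was compared between lateral habenula neuron-like cells and each other class in 120 tests, of which 3 passed, 0 with an estimated correlation (adjusted p = 0.928) and 8 with the library set as a term. Immediate early genes differed from fibroblast-like cells by −0.91 in median log2 fold change (adjusted p = 1.76e-04; 0.00234 with the set as a term). Oxidative phosphorylation genes differed from oligodendrocyte-like cells by 0.15 (adjusted p = 0.0275; 0.452 with the set as a term). Ribosomal protein genes differed from medial habenula neuron-like cells by 0.0872 (adjusted p = 0.0421; 0.00658 with the set as a term).

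CRS 1, CRS 2 and naive 1 stood apart from CRS 3, naive 2 and naive 3 on the first principal component of lateral habenula neuron-like cells, and the labels name no batch. The library names of CRS 1 and CRS 2 follow another pattern than that of CRS 3 and, unlike it, do not hold the letters CRS. Those of the naive libraries follow a single pattern. The sets parted in the other classes tested but for fibroblast-like cells, where naive 1 lay among the second set, and less clearly in microglia-like cells (r2 = 0.490 for the sets) and cluster 17 (0.307). The depth of the summed totals as the whole cause is argued against in lateral habenula neuron-like cells, where 1786 genes differed between the sets after thinning to equal totals, against 2083 before. Thinning did not equalise the UMIs per cell, so it cannot decide on depth per cell. Of the smaller classes, oligodendrocyte precursors had 131 genes higher and 128 lower in the second set before and 128 and 119 after thinning. Depth stays open in others, where fewer genes were called after thinning, from 299 higher and 485 lower in the second set to 88 and 131 in choroid plexus cells, from 94 and 473 to 3 and 62 in cluster 17, from 32 and 2 to 16 and 1 in microglia-like cells and from 26 and 9 to 0 in fibroblast-like cells. In lateral habenula neuron-like cells, RNA from other cells is argued against for the genes lower in the second set, of which 37.2% had a higher CPM outside the class (34.8 to 39.7, exact 95% interval), but it may account for part of those higher, of which 58.3% did (53.9 to 62.6; 47.4% of all genes tested). A difference between library batches in every droplet is a candidate explanation, since 1317 of the 1418 of these genes measured in oligodendrocyte-like cells moved the same way between the sets there (92.9%). The share was lower in fibroblast-like (83.7% of 405) and microglia-like cells (79.3% of 324), and the latter lay below the 80% set for oligodendrocyte-like cells. The split crosses the groups, and no biological explanation was tested.

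Oxidative phosphorylation genes were higher in CRS in lateral habenula neuron-like cells, with 64 of 75 higher within the first set and 59 of 75 within the second. The median difference was 0.000895 from naive 1 to CRS 1, 0.46 from naive 1 to CRS 2, 0.33 from naive 2 to CRS 3 and −0.0509 from naive 3 to CRS 3, so that the rise within each set came from pairs with CRS 2 or naive 2. In this class CRS 2 had the lowest and naive 2 the highest median UMIs per cell (4033 and 7074). CRS 1 also lay below naive 1 (4517.5 against 6289), without a rise in these genes. Depth per cell as a cause was not tested. The library sets as the whole cause are argued against, since the list was still called with the set as a term (adjusted p = 1.72e-04; median 0.19 against 0.18 without it) and its median differed by 0.02 between the sets. Members that move together between libraries whatever the group stay a candidate explanation, since the adjusted p was 0.876 with an estimated correlation and 6 of the 9 other splits called the list, with a median of up to 0.38 in size against 0.18. Between the 2 libraries of the same group in a set, the median differed by −0.53 and −0.45. More cytoplasmic RNA left with the CRS cells stays open, since the mitochondrially encoded genes had a median of 0.14 with the set as a term and −0.17 without it. The nuclear transcript Malat1 went against it in the first set, with 5.92% and 7.56% of UMIs in CRS 1 and CRS 2 and 4.28% in naive 1. In the second set CRS 3 (3.99%) lay between naive 2 (3.18%) and naive 3 (4.47%). An effect of stress on the neurons stays open as well and was untested.

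The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 genes in each class by edgeR, as few as any, so all 10 splits gave at least as many; the count at an unadjusted p under 0.05 was 572 by edgeR and 343 by DESeq2 in lateral habenula neuron-like cells. The highest other split was that of the library sets in each class, with 2083 genes in lateral habenula neuron-like, 3434 in medial habenula neuron-like, 2817 in astrocyte-like, 2383 in oligodendrocyte-like, 784 in choroid plexus, 259 in oligodendrocyte precursor, 34 in microglia-like and 35 in fibroblast-like cells, 1966 in cluster 12 and 567 in cluster 17, which points to a structure of the samples. For gene lists, the real count, the highest other count and the number of splits with at least the real count were 7, 10 and 5 in lateral habenula neuron-like, 4, 13 and 8 in medial habenula neuron-like, 2, 8 and 9 in astrocyte-like, 1, 7 and 9 in oligodendrocyte-like, 0, 9 and 10 in oligodendrocyte precursor, 1, 7 and 7 in microglia-like, 3, 3 and 2 in fibroblast-like and 3, 4 and 4 in choroid plexus cells, 2, 6 and 9 in cluster 12 and 1, 5 and 7 in cluster 17. The split of the library sets called 7 lists in lateral habenula neuron-like, 10 in medial habenula neuron-like, 7 in microglia-like and 7 in oligodendrocyte precursor cells, 5 in cluster 12, 2 in oligodendrocyte-like cells and 1 in cluster 17, as many as the real split or more, and fewer than the real split in astrocyte-like (0), choroid plexus (1) and fibroblast-like cells (2). For shares the counts were 0, 1 and 10.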

How the results depend on the processing

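The library set as a term, the fits within each set and fibroblast-like cluster 21 alone, also with an estimated correlation, were chosen after seeing the data; the other alternatives were planned. Over all alternatives, 1894 values stayed on their side of the threshold in the same direction, 177 were no longer past it, 11 came past it, 144 counts moved by over 1.5 times and 50 values changed sign; the cause was not tested except where fewer libraries were used. Nothing in the labels pairs the libraries, so the fit with the replicate number as a block stands as an alternative only. Libraries with the same number had correlations of 0.355, −0.414 and 0.321 across genes in lateral habenula neuron-like cells, where numbers 1 and 3 join libraries of the same set and number 2 libraries of different sets. In no class did every library correlate best with its own number; most did in microglia-like cells (5 of 6, with 0.224, 0.0127 and 0.117), oligodendrocyte precursors and cluster 17 (4 of 6 each). Settings that left a class under 20 cells in a library gave no gene or list value for it, while shares had no such limit. Where a group was left with 1 library, it was assumed to vary like the other group. Depth limited the smaller classes most, with 3288 genes testable in microglia-like and 4513 in fibroblast-like cells.

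With an estimated correlation, with directional fry, and with the set as a term and an estimated correlation, 0 gene lists passed in each class, as in fibroblast-like cluster 21 alone with an estimated correlation. Mixed fry, which reads change in either direction, had 0 but for 1 in choroid plexus cells. With the set as a term 5 lists passed in astrocyte-like, 2 in medial habenula neuron-like, 3 in oligodendrocyte-like and 1 in oligodendrocyte precursor cells, and 1 gene was higher and 2 lower in choroid plexus cells. With no filter on low counts, genes higher numbered 2 in astrocyte-like, 1 in fibroblast-like, 9 in lateral habenula neuron-like, 1 in microglia-like, 3 in oligodendrocyte-like and 1 in oligodendrocyte precursor cells and 1 in cluster 12, and genes lower 1 in choroid plexus and 3 in fibroblast-like cells and 1 in cluster 17; 1 list passed in fibroblast-like and 1 in oligodendrocyte precursor cells and 0 in cluster 17. With the replicate number as a block, 1 gene was lower in choroid plexus cells, and 1 list passed in oligodendrocyte precursor cells and 0 in cluster 17.

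Within CRS 1, CRS 2 and naive 1, genes higher and lower numbered 144 and 163 in astrocyte-like, 19 and 42 in choroid plexus, 57 and 115 in fibroblast-like, 31 and 22 in lateral habenula neuron-like, 771 and 498 in medial habenula neuron-like, 7 and 68 in microglia-like, 156 and 176 in oligodendrocyte-like and 14 and 29 in oligodendrocyte precursor cells, 3 and 2 in cluster 12 and 14 and 42 in cluster 17. Lists there numbered 2 in lateral habenula neuron-like, 1 in medial habenula neuron-like, 3 in microglia-like, 4 in oligodendrocyte-like and 2 in oligodendrocyte precursor cells, 0 in cluster 12 and 2 in cluster 17, and 2 classes passed in their share. Within CRS 3, naive 2 and naive 3, genes higher and lower numbered 12 and 3 in astrocyte-like, 4 and 2 in fibroblast-like, 1 and 1 in lateral habenula neuron-like, 4 and 1 in medial habenula neuron-like and 100 and 2 in microglia-like cells, 6 were higher in oligodendrocyte-like cells, and 36 and 66 in cluster 17; lists numbered 0 in microglia-like and 3 in oligodendrocyte-like cells and 3 in cluster 17.

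Without each library in turn, lists past the threshold ranged from 1 to 8 in lateral habenula neuron-like, 1 to 10 in medial habenula neuron-like, 1 to 6 in astrocyte-like, 1 to 3 in choroid plexus, 1 to 2 in fibroblast-like, 0 to 5 in microglia-like, 1 to 4 in oligodendrocyte-like and 0 to 4 in oligodendrocyte precursor cells, 0 to 7 in cluster 12 and 0 to 3 in cluster 17. Genes ranged, with the higher value without CRS 3, from 0 to 7 higher and 0 to 13 lower in fibroblast-like, 0 to 13 lower in microglia-like and 0 to 8 higher and 0 to 1 lower in oligodendrocyte precursor cells. In lateral habenula neuron-like cells the adjusted p ranged from 0.413 to 0.982 for core autophagy, 0.212 to 0.839 for autophagy receptors, 0.369 to 0.994 for mTORC1 and AMPK, 0.00268 to 0.215 for mitochondrially encoded genes and 2.19e-09 to 0.994 for ribosomal proteins, and for these in cluster 17 from 1.55e-05 to 0.907, each with a direction that turned in at least 1 case. The log2 fold change ranged from −0.11 to 0.0476 for Atg7, −0.0235 to 0.0396 for Gria2, −0.00338 to 0.20 for Map1lc3b, −0.30 to 0.25 for Tfeb, −0.30 to 0.000723 for Ulk1 and, in astrocyte-like cells, −0.0406 to 0.15 for Kcnj10. The log2 ratio of the share ranged from −0.0422 to 0.12 for astrocyte-like, −1.34 to 0.71 for choroid plexus, −0.14 to 3.730 for hippocampal or cortical neuron-like, −0.13 to 0.016 for lateral habenula neuron-like, −0.078 to 0.30 for microglia-like and −0.20 to 0.63 for mural cells.

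Signs also turned for Gria2 with DESeq2 (−0.0104), its size factors (−0.00143) and the set as a term (−0.000712), for Atg7 with 2 times the doublets removed (0.0321) and the set as a term (0.00099), and for Grin2a with the set as a term (0.0244). The share turned for astrocyte-like cells with TMM (−0.0128) and the stricter cell filter (−0.0182), for oligodendrocyte precursors with TMM (−0.00387), for hippocampal or cortical neuron-like cells with 2 times the doublets removed (−2.603, on 16 cells), and for ependymal cells with the set as a term (1.65) and the replicate block (0.20). The lists of core autophagy and of mTORC1 and AMPK genes in lateral habenula neuron-like cells, not called in any of these, turned with all neuron-like cells (adjusted p = 0.830 and 0.667), directional fry (0.965 for both), the set as a term (0.650 for both) and also an estimated correlation (0.869 for both), and the latter with no filter on low counts (0.871).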

Other observations

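The tests of the glucocorticoid response genes below were chosen after the result was seen, except leaving out each library, which was set down before.

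Glucocorticoid response genes, which the stress hormone corticosterone induces through its receptor, were higher in CRS in astrocyte-like, oligodendrocyte-like and medial habenula neuron-like cells once the library set was a term. The list had a median log2 fold change of 0.26 in astrocyte-like (24 genes, adjusted p = 1.003e-04), 0.40 in oligodendrocyte-like (8.62e-05) and 0.13 in medial habenula neuron-like cells (9.56e-04), and 0.04 in lateral habenula neuron-like cells (0.891). With an estimated correlation the adjusted p was 0.258, 0.885, 0.866 and 0.894 in this order. In the other classes, medians are given without the set as a term, over the genes also measured in lateral habenula neuron-like cells. They were 0.25 in choroid plexus and 0.04 in fibroblast-like cells. In oligodendrocyte precursors the median was −0.02, in microglia-like cells −0.09, and in clusters 12 and 17 −0.06 each. In oligodendrocyte-like cells Sgk1 (ENSMUSG00000019970), a kinase induced by the hormone, had 310.6 ± 46.5 CPM in naive and 405.6 ± 48.2 in CRS libraries (SD, n = 3), and Fkbp5, a co-chaperone of the receptor, had 21.9, 15.0 and 64.1 CPM in CRS 1, CRS 2 and CRS 3 and 11.03, 26.1 and 21.9 in naive 1, naive 2 and naive 3. In astrocyte-like cells Fkbp5 had 6.11, 7.71 and 45.4 and 4.27, 15.5 and 16.6 CPM. In fibroblast-like cells it went the other way, from a mean of 558.2 CPM in naive to 408 in CRS libraries. In lateral habenula neuron-like cells Sgk1 had 47.8 ± 0.869 CPM in naive and 47.9 ± 5.16 in CRS libraries. These genes were chosen after their values were seen.

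Weighed in astrocyte-like cells, the list was no longer called without CRS 3 (adjusted p = 0.0636), but its median was 0.33 there against 0.26 with all libraries. The call ended where only CRS 1, CRS 2 and naive 1 were left to compare the groups within a set. Without CRS 1, CRS 2, naive 1, naive 2 or naive 3 the list stayed called, with medians of 0.30, 0.28, 0.36, 0.32 and 0.34. Whether a single library was the whole cause of the shift in astrocyte-like cells cannot be told, since the list was not called without CRS 3. The median stayed positive whichever library was left out, but the measure of this test was the adjusted p and not the median. Whether the call itself rests on CRS 3 cannot be told. In oligodendrocyte-like cells the median without CRS 3 was 0.10 against 0.40 (adjusted p = 0.627) and in medial habenula neuron-like cells 0.17 against 0.13 (0.105). Members that move together between libraries whatever the group stay a candidate explanation, since the adjusted p with an estimated correlation was 0.258. The medians within the sets were 0.34 and 0.36, with 16 of 24 genes higher in the first and 21 of 26 in the second. The median difference was 0.26 from naive 1 to CRS 1, 0.48 from naive 1 to CRS 2, 0.36 from naive 2 to CRS 3 and 0.29 from naive 3 to CRS 3, and −0.0294 and −0.0401 between the 2 libraries of the same group in a set. An effect in 1 set alone still cannot be told apart from an effect in both, since each set holds a group with 1 library, whose own deviation is not measured. An effect of stress stays open and was untested.

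Cluster 22, of the lateral habenula class, was led by Fosb, Fos, Npas4, Junb, Egr1, Nr4a3 and Arc, genes that neuronal activity induces, with Fos at 466.3 CPM, and made up 0.837% ± 0.268 of cells in CRS and 1.01% ± 0.229 in naive libraries. Cluster 28 was led by genes that include Sag, Gnb3, Cngb3 and Mpp4, which photoreceptors and pinealocytes express, and 96 of its 181 cells came from CRS 1. Cluster 27, with 208 cells, was led by genes that include Fth1, Cryab, Mal, Cnp, mt-Co1 and mt-Cytb. It had 8 oligodendrocyte markers at 2-fold and was left unnamed because of its low UMI counts (median 1104) and because no oligodendrocyte marker of the list was among its 10 leading genes.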
